A study of Mus musculus with 10 samples.

How the data were processed

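RNA was measured by sequencing in 10 libraries of mouse cells that the labels call post-mortem fibroblasts, taken from ear or lung at 0 h or 12 h. There were 3 ear libraries and 2 lung libraries at each time. Per the labels, RNA was extracted with a Qiagen kit that recovers DNA and RNA together, and libraries were made with standard Illumina protocols. The authors deposited 1 table of TPM, a length-corrected share of a library's transcripts on a fixed scale, with a value for each of 61440 transcripts in each library. Per the submitters' processing notes, these values came from kallisto 0.44.1, which assigns reads to transcripts without a full alignment, and the genome build was GRCm38. The transcript set behind the kallisto index, its bias correction and any trimming of reads are not given in the sources used here.

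Each column of the table summed to the same total, so the values are shares of a library's transcripts after correction for length. TPM keeps no record of how many reads lie behind a value. The depth of each library is therefore unknown, and no counting interval or detection floor was computed. A rise in an abundant transcript lowers the share of every other transcript, and genes that share reads with a paralog or pseudogene depend on how kallisto divided those reads.

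Transcripts were matched to the GENCODE vM21 annotation by Ensembl ID without its version. Of the 61440 transcripts, 60503 matched, 56128 of them with the same version, and 937 did not. The unmatched transcripts held 0.508% to 0.590% of the TPM of a library and were not analysed further. TPM was summed per gene over 22594 genes, of which 21830 were protein-coding. Of the matched transcripts, 98.4% belonged to protein-coding genes, so most noncoding genes were not measured. Gene positions are those of GENCODE vM21 on GRCm38.

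Genes with at least 1 TPM in at least 2 libraries were tested, which left 13188 genes. Values were analysed as log2(TPM + 1), so fold changes are on that scale, which understates the change of genes near or below 1 TPM. A linear model with 1 mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level (eBayes with trend). The fit had 6 residual degrees of freedom and 3.23 prior degrees of freedom. All groups share its estimate of the spread, which the 2 lung libraries per time make necessary. A gene near 0 in 1 tissue varies little there, which can lower its shared spread and its SE in the other tissue. The contrasts were 12 h against 0 h in ear, 12 h against 0 h in lung, the difference between these (the interaction of tissue and time), and lung against ear at 0 h and at 12 h. P values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All tests were two-sided.

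The labels do not say that the replicates of a group came from separate animals. Every p therefore measures the spread between these libraries only, and part of that spread may be technical.

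In all, 38 gene lists were written before the data were examined, and so were the tests, the threshold, the filters, the rule for named genes and most alternatives. The lists cover stress, metabolic, inflammatory and proliferation pathways, matrix and contractile genes, transcription factor genes of lung mesenchyme and of skin, head and neural crest mesenchyme, Hox genes, and markers of fibroblasts and of other cell types. Each was tested with limma's camera, which asks whether the genes of a list rank higher or lower than the other genes, with a preset correlation of 0.01 between the genes of a list and adjustment over the lists within a contrast. Of the 38 lists, 37 could be tested. Of the 12 lymphocyte markers, 0 passed the filter. The Hox list holds 15 genes of the A and B clusters only, and list results for Hox genes refer to these. A gene near 0 in 1 tissue or time passes the filter through the other libraries, so its direction is then partly built in. List results cover only the genes that passed it: 11 of 20 skin, head and neural crest genes, 3 of 10 alveolar, 9 of 14 epithelial, 9 of 12 skeletal muscle, 9 of 12 chondrocyte, 8 of 12 endothelial, 8 of 11 smooth muscle, 5 of 9 mesothelial, 5 of 10 melanocyte and Schwann and 9 of 10 adipocyte markers, 14 of 15 Hox genes, 22 of 24 interferon-stimulated genes, 15 of 16 immediate early genes, and every gene of the other lists tested. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation, 0 list calls remained for 12 h against 0 h in either tissue or for the interaction. For lung against ear, 2 remained at 0 h and 1 remained at 12 h. The estimated correlation was 0.968 for G2/M genes and 0.835 for macrophage and for skeletal muscle markers. In such lists the preset of 0.01 treats genes that move together as nearly independent. For lists in the time contrasts and the interaction, words such as rose and fell describe medians and the preset test only. For each list the number of its tested genes past the threshold is given over all genes and adjusted over the list alone.

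The genes named were chosen by a rule. For the ear and lung time contrasts and for lung against ear at 0 h, it took up to 8 genes in each direction with the largest fold change among genes past the threshold, with libraries of the 2 groups that did not overlap and a mean of at least 5 TPM. Where fewer passed, the places were filled by the smallest p under the same conditions, and these genes are given as values and not as changes. For the interaction it took 4 genes in each direction without the condition on overlap. It also took up to 4 genes with the smallest p from each list that passed the list test or held a gene past the threshold. Predicted genes and pseudogenes recognisable by name were left out. Y-linked genes were read to check the libraries.

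The fit was tested on simulated data in which each gene had 1 spread, that of the fit, in all 10 libraries. Of 13188 genes, 100 were changed 2-fold and 100 more 4-fold, drawn from genes with a mean level of about 5 TPM or more. The shares recovered may therefore not hold for lower genes. At 2-fold, 51% were recovered for the ear time contrast, 18% for the lung time contrast and 28% for lung against ear at 0 h. At 4-fold the shares were 86%, 74% and 87%. Between 0.02% and 0.07% of unchanged genes were called. In each of these simulated contrasts, 1 list of 1 raised 2-fold was called and 0 of 36 unchanged lists were. The simulated genes varied independently, whereas genes of some real lists move together. The count of unchanged lists called therefore does not measure the rate of false list calls in these data.

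The alternatives set beforehand were no filter (18812 genes), a filter of 5 TPM (10683 genes), no trend in the variances, quantile normalization, upper-quartile scaling, a pseudocount of 0.1, leaving out each of the 10 libraries in turn, fitting a tissue or a time alone, and the replicate number within a tissue as a block, which left 3 residual degrees of freedom. Added after the data were seen were a term for the 2 libraries that hold Y-linked transcripts, leaving those 2 out, limma's array weights, a test of 27764 transcripts in place of genes, a block that joined lung number 1 at 0 h to lung number 2 at 12 h, and the replicate number within a time as a block across tissues. A fit that leaves out a lung library has 1 library in a group, whose spread is assumed to be that of the other groups. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. Reads were not used here.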

Results

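The data were transcript levels of mouse cells that the labels call fibroblasts, the connective tissue cells that make and remodel extracellular matrix, taken from ear or lung at 0 h or 12 h after death. There were 3 libraries for each ear time point and 2 for each lung time point. The comparisons addressed how the expression profile differed between the times in each tissue, whether that difference was shared by the tissues, and how lung and ear cells differed from each other. Each library held 12024 to 12337 genes at 1 TPM or more, and the sequencing depth behind these values is unknown. Transcripts encoded by mitochondrial DNA took 0.641% to 1.297% of TPM, and the 100 most abundant genes took 34.7% to 39.2%.

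Tissue of origin separated the libraries along the first principal component, which held 65.3% of the variance. Lung libraries scored -49.6 to -85.3 on it and ear libraries 38.9 to 54.3. Correlations across genes were 0.808 to 0.915 between libraries of different tissues, 0.947 to 0.984 within a group, and 0.945 to 0.990 between the times of a tissue, so libraries of different times were as alike as libraries of the same time. Ear libraries of equal replicate number were more alike than other combinations, which was not tested. After group means were removed, ear libraries with the same number correlated at 0.453, 0.320 and 0.377, and the other combinations lay between -0.491 and 0.266. In lung, libraries with the same number correlated at -0.443 and those with different numbers at 0.443. With 2 libraries per group these are 1 value with its sign turned, so they cannot be weighed against other combinations. The Y-linked genes Ddx3y and Eif2s3y were at 52.5 and 28.9 TPM in ear 0 h number 2 and at 53.3 and 32.9 TPM in lung 0 h number 2. Elsewhere Ddx3y was highest, at 0.758 TPM, in lung 12 h number 1. Ear 0 h number 2 thus held Y-linked transcripts that ear 12 h number 2 lacked, although their numbers match.

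**Figure D1:**
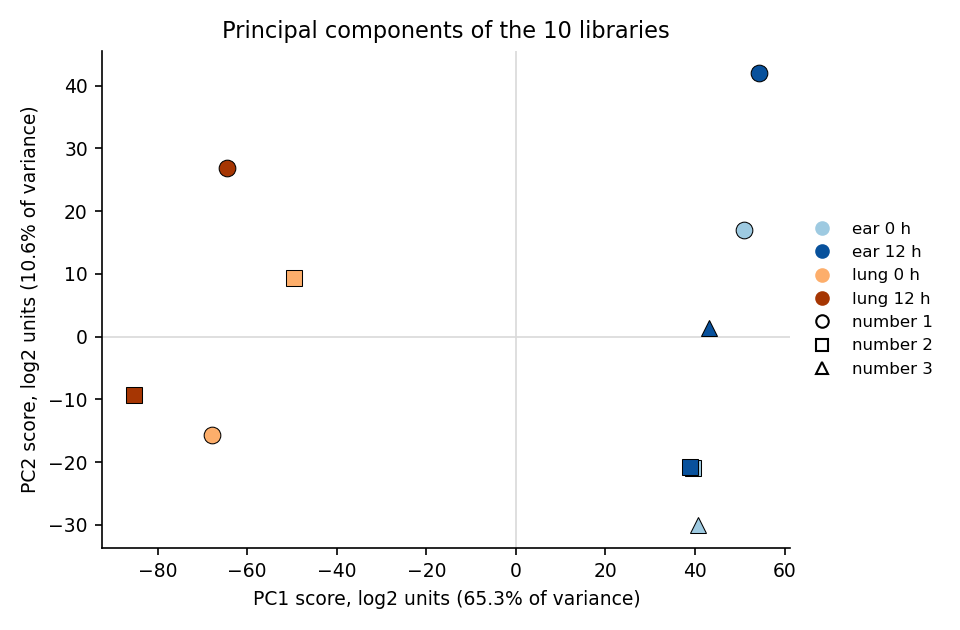
Scores of the 10 libraries on principal components 1 and 2 of log2(TPM + 1), in log2 units, with colour for group and marker shape for replicate number. Lung libraries lie at -85.3 to -49.6 on PC1 and ear libraries at 38.9 to 54.3, while PC2 (10.6% of variance) ranges within a tissue, from -30.1 to 42.0 in ear.

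Comparative analysis of lung and ear at 0 h revealed that genes of mesenchymal positional identity differed between the tissues. Foxf1, which encodes a forkhead factor of lung mesenchyme, was at 20.8 ± 2.83 TPM in lung and 0.472 ± 0.177 TPM in ear (mean ± SD, n = 2 and 3; log2 fold change 3.89, SE 0.194, adjusted p = 1.05e-05). Tbx2, Tbx4 and Foxf2, further transcription factor genes of lung mesenchyme, were higher in lung by 3.62, 4.81 and 3.11. Of the 12 genes in the lung mesenchyme list, 10 were higher in lung over all genes and 11 adjusted over the list alone (camera adjusted p = 2.13e-14; adjusted p = 0.0249 with an estimated correlation). Tbx15, a T-box factor gene of skin and head mesenchyme, was at 36.5 ± 2.28 TPM in ear and 0.435 ± 0.0165 TPM in lung (log2 fold change -4.71, SE 0.251, adjusted p = 1.55e-05), and Twist1 and Msx1 were lower in lung by -3.86 and -3.26. Of the 20 genes of the skin, head and neural crest list, 11 passed the filter, and these 11 were lower in lung, over all genes and adjusted over the list alone (median -2.47, camera adjusted p = 1.06e-14; adjusted p = 0.0056 with an estimated correlation). Without the filter that median was -1.18, and with a pseudocount of 0.1 it was -3.91. Hox genes encode factors that specify position along the body axis, and those of the A and B clusters were listed. Over all genes, 12 of 14 of these were higher in lung, and adjusted over the list alone 12 were higher and 1 lower (camera adjusted p = 6.80e-16; adjusted p = 0.180 with an estimated correlation). Hoxb2, Hoxb4 and Hoxb6 were higher by 3.25, 3.11 and 3.83, and Hoxa5 was at 14.7 TPM in lung and listed at 0 in all 3 ear 0 h libraries. Foxf1 (ENSMUSG00000042812.5) lies on chromosome 8 at 121084386 to 121088144, and Tbx15 (ENSMUSG00000027868.11) on chromosome 3 at 99240381 to 99354259.

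**Figure D2:**
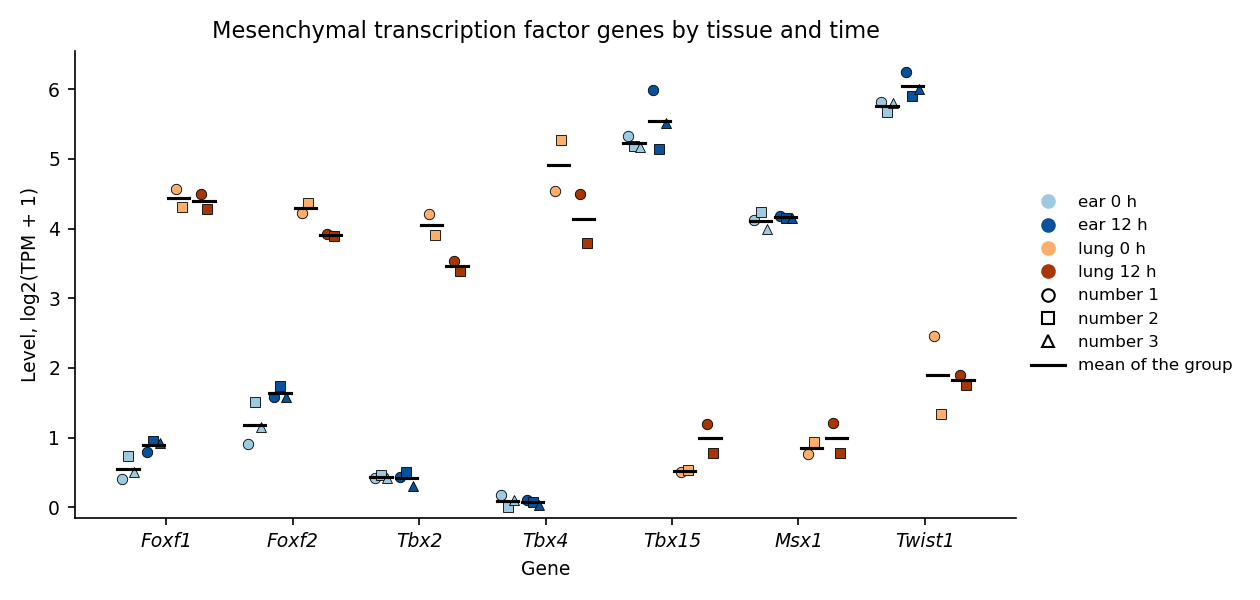
Levels of mesenchymal transcription factor genes in log2(TPM + 1), with a point for each library and a line at the mean of each group. Foxf1, Foxf2, Tbx2 and Tbx4 lie higher in every lung library than in any ear library, and Tbx15, Msx1 and Twist1 lie lower, at both times; at 0 h the log2 fold changes ran from -4.71 for Tbx15 to 4.81 for Tbx4.

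Macrophage transcripts were higher in lung. Lyz2, which encodes the lysozyme of myeloid cells, was at 5406 ± 892 TPM in lung at 0 h and 18.3 ± 5.57 TPM in ear (log2 fold change 8.16, SE 0.365, adjusted p = 7.90e-06). The chemokine genes Ccl6 and Pf4, the signalling adaptor gene Tyrobp and the lectin receptor gene Clec4n were higher in lung by 7.93, 7.17, 6.995 and 6.55. Plac8 and Cck were higher by 6.74 and 6.58, and Clec7a, another lectin receptor gene, was at 95.8 TPM in lung and 0.131 TPM in ear. Of the 14 macrophage and myeloid markers, 11 were higher in lung over all genes and 14 adjusted over the list alone, with a median of 3.44 (camera adjusted p = 1.43e-16; adjusted p = 0.262 with an estimated correlation). Lyz2 (ENSMUSG00000069516.8) lies on chromosome 10 at 117277331 to 117282321. It has a close paralog, so the division of shared reads is uncertain. Of 10 alveolar and airway epithelial markers only 3 passed the filter. These were also higher in lung, 2 of 3 over all genes and 3 adjusted over the list alone (median 1.15, camera adjusted p = 8.50e-04; adjusted p = 0.118 with an estimated correlation). The 3 summed to 0.997 to 2.07 TPM in ear libraries and 7.60 to 10.4 TPM in lung libraries. They thus passed the filter largely through lung, which nearly built in their direction. The surfactant gene Sftpc was at 4.44 ± 1.73 TPM in lung at 0 h. The Ager log2 fold change, lung vs ear at 0 h, was 0.95, and its call was lost without lung 0 h number 1 (0.88) and without number 2 (1.02).

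Among the genes lower in lung at 0 h, Il1rl1, which encodes the receptor for interleukin 33, was at 1581 ± 469 TPM in ear and 7.03 ± 1.15 TPM in lung (log2 fold change -7.58, SE 0.328, adjusted p = 7.90e-06). Ly6a, which encodes the surface antigen Sca-1, was at 2117 ± 680 TPM in ear and 19.5 ± 5.94 TPM in lung (log2 fold change -6.68, SE 0.387, adjusted p = 2.11e-05). It belongs to a family of similar genes that may share reads. Chil1, Angptl7, Il16, Aldh1a7 and Rpl39l were lower in lung by -6.53, -5.80, -5.50, -5.42 and -5.31. The Rarres2 log2 fold change, lung vs ear at 0 h, was -5.48, and its call was lost without lung 0 h number 1 (-4.96), lung 0 h number 2 (-6.01), ear 0 h number 1 (-4.83) or ear 0 h number 3 (-5.38). Il1rl1 (ENSMUSG00000026069.15) lies on chromosome 1 at 40429570 to 40465415.

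Contractile genes and markers of other cell types divided the tissues as well. Of 18 myofibroblast and TGF-beta target genes, 11 were higher in lung at 0 h over all genes and 15 adjusted over the list alone, with a median of 2.02 (camera adjusted p = 1.02e-11; adjusted p = 0.272 with an estimated correlation). Cnn1 and Actg2, which encode smooth muscle calponin and gamma actin, rose from 9.46 ± 9.83 to 388 ± 59.2 TPM and from 18.9 ± 11.7 to 929 ± 20.3 TPM between ear and lung (5.61 and 5.71), and Ankrd1 was higher by 4.49. The Tpm1 log2 fold change, lung vs ear at 0 h, was 2.29, and it lost its call without lung 0 h number 1 (2.28). Of 8 smooth muscle and pericyte markers, 4 were higher and 1 lower over all genes, and 5 and 1 adjusted over the list alone (median 1.74, camera adjusted p = 0.0023; adjusted p = 0.262 with an estimated correlation), with Myh11, Kcnj8 and Des higher by 4.78, 4.75 and 4.73. Of 14 fibroblast markers, 4 were lower in lung and 1 higher over all genes, and 5 and 1 adjusted over the list alone (median -0.88, camera adjusted p = 0.0053; adjusted p = 0.358 with an estimated correlation). Dpt, Thy1 and S100a4 were lower by -4.65, -3.87 and -3.11, and the list's median was -0.39 without lung 0 h number 1. Of 9 chondrocyte markers, genes of cartilage cells, 4 were lower in lung over all genes and 8 adjusted over the list alone (median -2.98, camera adjusted p = 9.63e-06; adjusted p = 0.397 with an estimated correlation). Sox9 was at 22.2 ± 4.18 TPM in ear and 0.359 TPM in lung, and Hapln1 was lower by -2.98.

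Further lists were called at 0 h. Interferon-stimulated genes were lower in lung for 7 of 22 genes over all genes, and adjusted over the list alone 12 were lower and 1 higher (median -0.96, camera adjusted p = 7.62e-05; adjusted p = 0.521 with an estimated correlation), with Ifit2 at -1.66. The interferon median was -1.45 with a filter of 5 TPM and -0.60 without lung 0 h number 1. Cholesterol biosynthesis genes were lower for 5 of 22 genes over all genes and 11 adjusted over the list alone (median -0.58, camera adjusted p = 3.85e-05; adjusted p = 0.653 with an estimated correlation). The hypoxia list, targets of the oxygen-sensing HIF factors, had 3 of 22 genes higher over all genes and 5 adjusted over the list alone (median 0.64, camera adjusted p = 0.0014; adjusted p = 0.732 with an estimated correlation), and glycolysis had 2 of 16 and 4 (median 0.49, camera adjusted p = 0.0025; adjusted p = 0.732 with an estimated correlation). Both of these lost their calls without lung 0 h number 2, with medians of -0.00 and 0.18, and the hypoxia median was 1.15 without lung 0 h number 1. Hk2, the glycolytic hexokinase gene, was higher by 2.08. Epithelial and keratinocyte markers had 5 of 9 genes higher and 1 lower over all genes, and 7 and 1 adjusted over the list alone (median 1.52, camera adjusted p = 0.0053; adjusted p = 0.505 with an estimated correlation), with Krt18 at 2.91 and Trp63 at -2.88. This call was lost with a filter of 5 TPM (2.13), and the median was 0.43 without the filter. Adipocyte markers had 0 of 9 genes past the limma threshold over all genes and 0 adjusted over the list alone (median -1.42, camera adjusted p = 0.0247; adjusted p = 0.732 with an estimated correlation). That call was lost without lung 0 h number 2 (-1.30) and its median was -2.15 with a filter of 5 TPM, -2.33 with a pseudocount of 0.1 and -0.54 without ear 0 h number 1, which held Plin1, a lipid droplet gene, at 220 TPM against 4.43 and 7.45 TPM in the other ear 0 h libraries.

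Among lists that did not pass at 0 h, some held genes that differed. Of 28 collagen and matrix genes, 5 were lower in lung over all genes and 7 adjusted over the list alone (median -0.54), with the microfibrillar collagen gene Col6a2 at -3.04. Of 24 NF-kB and cytokine genes, 5 were higher in either count (0.18), with the cytokine genes Il1a at 2.69 and Lif at 1.64. Matrix proteases and inhibitors had 4 genes higher and 3 lower over all genes, and 4 and 5 adjusted over the list alone, with a median of -0.28 and a mean of 0.22. Mmp10 and Mmp9, which encode matrix metalloproteinases, were higher by 4.45 and 4.57. Mesothelial markers had 2 genes higher and 2 lower in either count, with a median of 0.71 and a mean of -0.69, and Msln was lower by -4.98. Senescence genes had 3 higher and 1 lower over all genes, and 7 and 3 adjusted over the list alone (0.47). The medians of the other lists that did not pass lay between -0.38 for skeletal muscle and 0.47 for melanocyte and Schwann markers.

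In limma's test of lung against ear at 0 h, 1488 of 13188 genes passed the threshold, 806 higher and 682 lower in lung, 1241 of them at 2-fold or more. The count was 549 without lung 0 h number 1 and 890 without lung 0 h number 2, and 745 with the replicate number within a time as a block across tissues. At 12 h, 2267 genes passed, 1064 higher and 1203 lower, and 1369 without lung 12 h number 2. With that block the 12 h count was 1164. More genes were higher than lower at 12 h with quantile normalization (1280 and 1121) and with upper-quartile scaling (1207 and 1147). Of the genes called at each time, 653 were higher in lung at both, where 65.0 would be shared if the calls were independent. Another 546 were lower at both (62.2 if independent), and 0 differed in opposite directions. The 2 contrasts compare the same tissues and share each gene's spread, so their calls could not be independent and the excess decides nothing.

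At 12 h the same identity groups separated the tissues. Foxf1, Tbx4 and Hoxa5 were higher in lung by 3.49, 4.07 and 3.46, and Tbx15, Twist1 and Msx1 lower by -4.56, -4.22 and -3.17. The skin, head and neural crest list was lower for 10 of 11 genes over all genes and 10 adjusted over the list alone (median -2.55, or -1.08 without the filter; camera adjusted p = 3.29e-11; adjusted p = 0.0121 with an estimated correlation). Lung mesenchyme genes were higher for 9 of 12 over all genes, and 10 were higher and 1 lower adjusted over the list alone (median 2.01, camera adjusted p = 1.01e-08; adjusted p = 0.0941 with an estimated correlation). Hox genes of the A and B clusters were higher for 11 of 14 and lower for 1, in either count (median 2.51, camera adjusted p = 5.44e-11; adjusted p = 0.307 with an estimated correlation). Macrophage markers were higher for 13 of 14 genes over all genes and 14 adjusted over the list alone (median 5.80, camera adjusted p = 7.01e-19; adjusted p = 0.264 with an estimated correlation), and Lyz2 was at 10085 ± 5141 TPM in lung. Myofibroblast genes were higher for 13 of 18 and 16 adjusted over the list alone (median 2.44, camera adjusted p = 3.29e-11; adjusted p = 0.324 with an estimated correlation), with Cnn1 at 6.54 and Actg2 at 7.08. All 9 skeletal muscle markers tested were lower in lung in either count (median -2.64, camera adjusted p = 5.46e-06, or 0.471 with an estimated correlation). Actc1 was at -4.43 and Tnnc2 at -3.79. The filter, passed largely through ear, partly built this in.

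The other lists called at 12 h had smaller medians or depended on a library, and with an estimated correlation each of their adjusted p values lay between 0.159 and 0.807. Cholesterol biosynthesis genes were lower for 7 of 22 over all genes and 13 adjusted over the list alone (median -0.69). Alveolar markers were higher for 3 of 3 in either count (1.24; 0.31 without the filter, 3.03 with a pseudocount of 0.1 and 0.81 without lung 12 h number 2). As at 0 h, these 3 had passed the filter largely through lung. Autophagy and lysosome genes were higher for 6 of 22 over all genes, and 10 higher and 1 lower adjusted over the list alone (0.58; 0.33 without lung 12 h number 2). Fibroblast markers had 6 of 14 lower and 1 higher over all genes, and 7 and 1 adjusted over the list alone (-1.71; -1.12 without ear 12 h number 1). Chondrocyte markers were lower for 4 of 9 in either count (-1.88; -1.04 without lung 12 h number 1, -1.22 without ear 12 h number 2, -0.86 without the filter, -0.80 with array weights and -3.21 with a pseudocount of 0.1). As at 0 h, these 9 had passed the filter largely through ear. Smooth muscle markers had 5 of 8 higher over all genes, and 5 higher and 1 lower adjusted over the list alone (1.52; 0.83 without the filter; call lost at 1.18 without lung 12 h number 1). Ribosomal protein genes were lower for 3 of 36 over all genes and 2 adjusted over the list alone (-0.26). Their call was lost with upper-quartile scaling (-0.19), with the block across tissues (-0.21), and without lung 12 h number 2 (-0.20) or ear 12 h number 3 (-0.21). Collagen and matrix genes were lower for 8 of 28 over all genes and 9 adjusted over the list alone (-0.73). It was lost without lung 12 h number 2 (-0.50), ear 12 h number 1 (-0.48) or ear 12 h number 2 (-0.85). Interferon-stimulated genes had 5 of 22 lower and 1 higher over all genes, and 6 and 1 adjusted over the list alone (-0.74). The interferon result was lost without either lung 12 h library (-0.82 and -0.74), without ear 12 h number 1 (-0.66) or without ear 12 h number 2 (-0.72). Mitochondrially encoded transcripts had 0 of 13 genes past the threshold in either count (0.40). This one was lost with quantile normalization (0.41), upper-quartile scaling (0.47), or without lung 12 h number 1 (0.01) or ear 12 h number 1 (0.21).

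Comparison of ear libraries at 12 h and 0 h showed higher values at 12 h for genes of the skeletal muscle contractile apparatus. Tnnc2, the fast troponin C gene, was at 1.49 ± 0.442 TPM at 0 h and 17.3 ± 13.6 TPM at 12 h (mean ± SD, n = 3; log2 fold change 2.65, SE 0.428, adjusted p = 0.468). Actc1, a sarcomeric actin gene, was at 2.35 ± 0.468 and 25.8 ± 16.3 TPM (2.82, SE 0.480, adjusted p = 0.468), and Myl1, a myosin light chain gene, at 5.04 ± 3.88 and 72.4 ± 62.9 TPM (3.46, SE 0.709, adjusted p = 0.767). Acta1, Tnnt3, Tnni2, Tnnc1 and Des had log2 fold changes of 2.51, 1.98, 2.28, 2.02 and 2.29. In these 8 genes every 12 h library lay above every 0 h library, which the rule that named them required. Of 12 skeletal muscle markers 9 passed the filter, and these 9 were higher at 12 h, with a median of 1.98 (camera adjusted p = 9.13e-30; adjusted p = 0.173 with an estimated correlation). Of the 9, 0 passed over all genes and 9 adjusted over the list alone. The spread behind that count is shared with the lung libraries, where the 9 summed to 5.05 to 13.9 TPM, so it may be too small for ear. Myog, which encodes a factor of muscle differentiation, was at 0.136 to 0.874 TPM at 0 h and at 3.25, 1.46 and 10.8 TPM at 12 h. It passed the filter through the 12 h libraries, so its direction was partly built in. Pax7, a muscle stem cell gene, was listed at 0 in all ear libraries. Tnnc2 (ENSMUSG00000017300.9) lies on chromosome 2 at 164777161 to 164779967 and Actc1 (ENSMUSG00000068614.7) on chromosome 2 at 114047282 to 114053548.

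**Figure D3:**
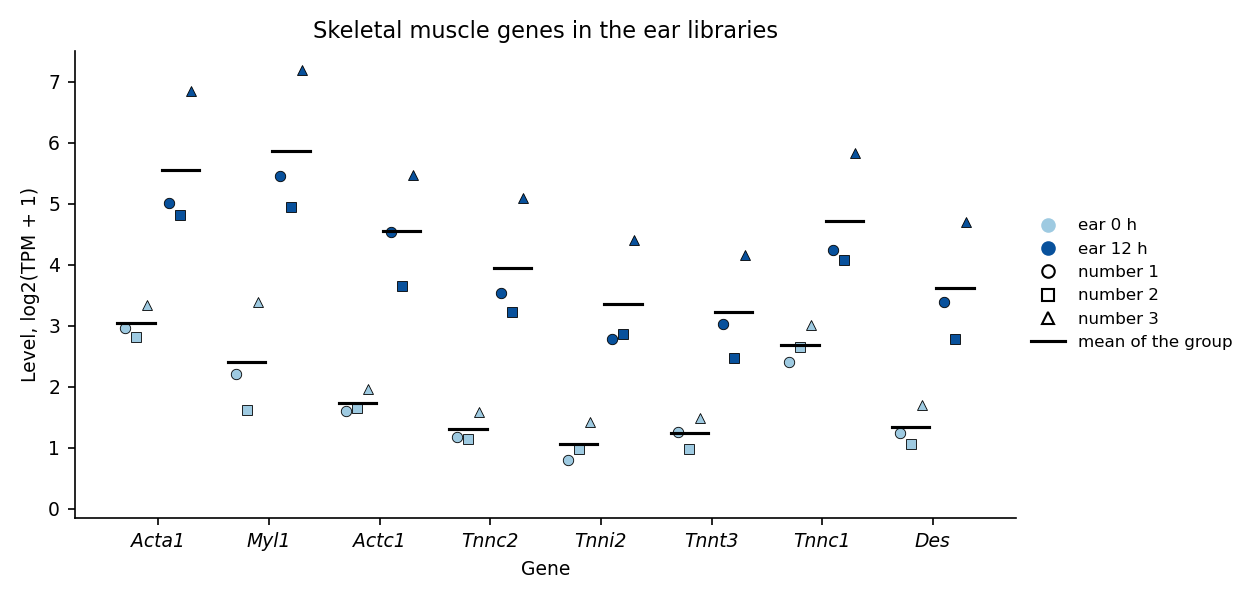
Levels of 8 skeletal muscle genes in the 6 ear libraries in log2(TPM + 1), with a point for each library and a line at the mean of each group. Each gene lies higher in all 3 libraries at 12 h than in any at 0 h, as the rule that named them required, and Myl1 is highest in 12 h number 3, at 145 TPM against 42.6 and 30.0 TPM in numbers 1 and 2.

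The genes with the smallest p among those lower at 12 h in ear had modest values. Apc, which encodes a brake on Wnt signalling, was at 18.9 ± 1.11 TPM at 0 h and 9.30 ± 1.36 TPM at 12 h (log2 fold change -0.96, SE 0.246, adjusted p = 1.00), and Ncaph2, a condensin subunit gene, at 241 ± 15.2 and 165 ± 16.9 TPM (-0.55). Klk10, Gsta4, Lrrc17, Fam53b, Lsg1 and Gtf2h4 had log2 fold changes of -1.64, -1.54, -0.67, -0.59, -0.56 and -0.54. In limma's test, 0 of 13188 genes passed the threshold for 12 h against 0 h in ear. Without adjustment, 219 genes (1.66%) had an unadjusted p under 0.05, 169 of them higher and 50 lower, and the smallest adjusted p was 0.468. The 1.66% is below the share of 0.05 that this threshold would pass on average if no gene changed.

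Proliferation genes were lower at 12 h in ear as lists, with the preset correlation only. All 22 genes of the G2/M list, which act in mitosis, had lower means at 12 h, with a median of -0.68 (camera adjusted p = 8.92e-09; adjusted p = 0.663 with an estimated correlation), and all 22 of the S phase and DNA replication list did, with a median of -0.42 (camera adjusted p = 1.67e-06; adjusted p = 0.663 with an estimated correlation). In each list 0 genes passed the limma threshold over all genes and 0 adjusted over the list alone. Aurka and Kif20a, genes of the G2/M list, had values of -0.88 and -0.82, and Cdc45 and Gins2, genes of the S phase list, of -0.61 and -0.52. The calls rested on ear 12 h number 1: without it the medians were -0.00 and -0.01 and both calls were lost. Without ear 12 h number 2 they were -1.20 and -0.84, and the S phase median was -0.65 without ear 0 h number 1 and -0.28 without ear 0 h number 3. Mki67, a marker of cycling cells, was at 16.4, 16.5 and 21.1 TPM at 0 h and at 3.13, 22.5 and 12.1 TPM at 12 h in numbers 1 to 3.

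**Figure D4:**
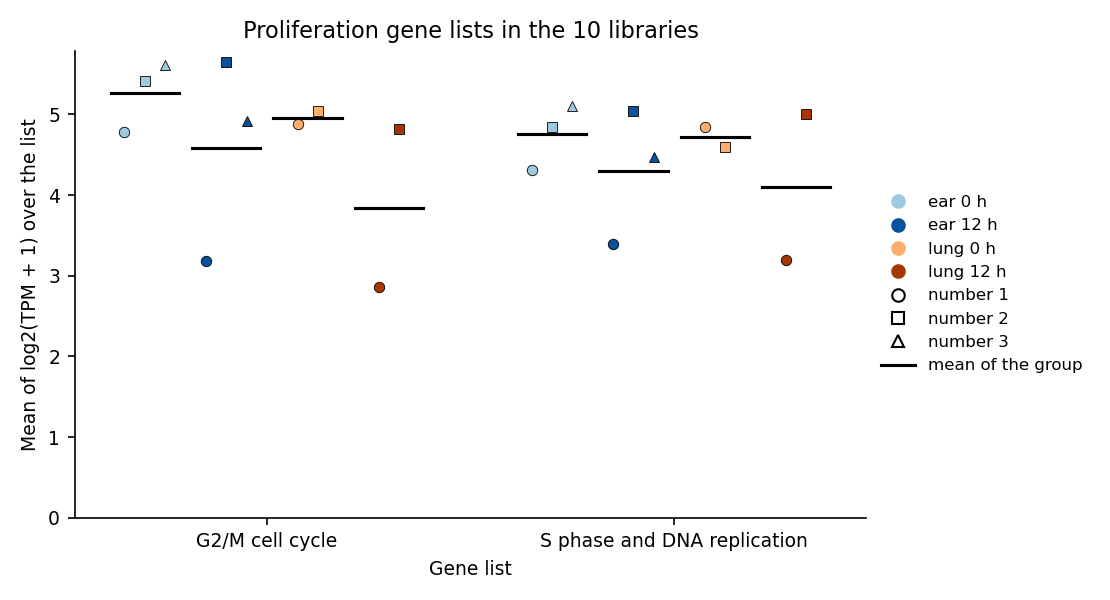
Mean of log2(TPM + 1) over the G2/M and the S phase gene lists in each library, with a line at the mean of each group. Ear 12 h number 1 (3.18 and 3.39) and lung 12 h number 1 (2.86 and 3.19) lie below the other libraries, which range from 4.78 to 5.65 for G2/M and from 4.31 to 5.11 for S phase.

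Hypoxia, glycolysis and inflammatory genes rose in ear as lists, each with 0 genes past the limma threshold over all genes and 0 adjusted over the list alone. Of 22 hypoxia genes, 21 had higher means at 12 h, with a median of 0.47 (camera adjusted p = 1.12e-05; adjusted p = 0.663 with an estimated correlation). The vasodilator peptide gene Adm was at 171 ± 22.2 and 344 ± 188 TPM and the angiogenic factor gene Vegfa at 61.1 ± 17.2 and 102 ± 38.4 TPM. The hypoxia median was 0.24 without ear 12 h number 1, 0.80 without ear 12 h number 2 and 0.27 without ear 0 h number 3. Glycolysis genes had a median of 0.23 (camera adjusted p = 0.0011; adjusted p = 0.663 with an estimated correlation), with Slc16a3, a lactate transporter gene, at 1.01. That call was lost without ear 12 h number 3 (0.14), ear 0 h number 2 (0.19) or ear 0 h number 3 (0.09), and the median was 0.44 without ear 0 h number 1 and 0.40 without ear 12 h number 2. Of 24 NF-kB and cytokine genes, 22 had higher means at 12 h, with a median of 0.45 (camera adjusted p = 4.00e-05; adjusted p = 0.490 with an estimated correlation). Il6, Ccl2, Csf3 and Cxcl12, which encode secreted inflammatory signals, had values of 1.55, 0.93, 1.62 and 0.82. The NF-kB median was 0.81 with a filter of 5 TPM and 0.80 with a pseudocount of 0.1. Immediate early genes had a median of 0.34 (camera adjusted p = 9.80e-04; adjusted p = 0.663 with an estimated correlation), with Ier3, Dusp1 and Junb at 0.69, 0.69 and 0.61. The immediate early call was lost without ear 12 h number 1 (0.03) and without ear 0 h number 1 (0.26), and the median was 0.63, 0.73 and 0.64 without ear 12 h number 2, ear 12 h number 3 and ear 0 h number 3.

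The hypoxia, glycolysis and NF-kB lists also followed a division of the ear libraries other than time, seen after the values were examined. The mean log2(TPM + 1) over the hypoxia list was 5.68, 6.14 and 5.91 in ear 0 h number 1, 12 h number 1 and 12 h number 3, and 5.18, 4.96 and 5.11 in ear 0 h number 2, 0 h number 3 and 12 h number 2. For glycolysis these means were 7.96, 7.93 and 7.88 against 7.22, 7.04 and 7.29, and for NF-kB and cytokine genes 4.80, 5.70 and 5.47 against 4.26, 4.52 and 4.40. The lists of senescence, fatty acid oxidation and antioxidant genes were likewise higher in each of the former 3 libraries than in any of the latter, and those of p53 targets, G2/M and S phase genes were lower. The fatty acid oxidation and antioxidant lists nevertheless fell with time, although the libraries where they were higher include 2 of the 3 at 12 h. Between libraries of equal number, the NF-kB mean was higher at 12 h in numbers 1, 2 and 3 (4.80 and 5.70, 4.26 and 4.40, 4.52 and 5.47). The hypoxia mean was higher in numbers 1 and 3 and lower in number 2, and the glycolysis mean was higher in numbers 2 and 3 and lower in number 1. Numbers 1 and 2 each lie within 1 side of the division and number 3 lies across it.

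Markers of other cell types differed between the times in ear as lists, with the preset correlation only. Chondrocyte markers fell, with a median of -0.97 and 0 of 9 genes past the limma threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 3.71e-06; adjusted p = 0.525 with an estimated correlation). Acan, Hapln1 and Cnmd, genes of cartilage matrix, had values of -1.67, -0.97 and -1.39, and the median was -0.34 without ear 0 h number 1, -0.41 without ear 12 h number 3 and -0.64 without the filter. Endothelial markers, genes of vessel-lining cells, rose with a median of 0.24, 0 of 8 genes over all genes and 2 adjusted over the list alone, while 4 of the 8 had lower means (camera adjusted p = 0.0034; adjusted p = 0.418 with an estimated correlation). Cdh5 was at 1.91 ± 1.19 and 8.62 ± 3.76 TPM, Pecam1 at 0.788 ± 0.376 and 2.15 ± 0.611 TPM, and Emcn had a value of 1.05. The endothelial call was lost without ear 12 h number 3 (0.21) or ear 0 h number 1 (0.27), and the median was 0.47 without ear 0 h number 2, 0.42 without ear 12 h number 2 and 1.14 with a filter of 5 TPM.

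Of the other lists called in ear, each had 0 genes past the limma threshold over all genes and 0 adjusted over the list alone. Ribosomal protein genes fell, with a median of -0.12 and 35 of 36 genes lower (camera adjusted p = 6.23e-08; adjusted p = 0.663 with an estimated correlation). The ribosomal call was lost without ear 0 h number 3 (-0.06), and the median was -0.23 without ear 0 h number 1 and -0.07 without ear 12 h number 1. Nuclear genes of oxidative phosphorylation fell (median -0.09, camera adjusted p = 4.00e-05; adjusted p = 0.652 with an estimated correlation). Without ear 12 h number 1 the call was lost (-0.05), and the median was -0.16 without ear 12 h number 3. Fatty acid oxidation genes fell (-0.11, camera adjusted p = 0.0020; adjusted p = 0.663 with an estimated correlation). Their call was lost without ear 12 h number 2 (-0.04), and the direction turned without ear 0 h number 1 (0.07). That library also held the highest adipocyte markers, with a mean log2(TPM + 1) of 5.63 against 2.72 and 2.69 in the other ear 0 h libraries. The median was -0.24 without ear 0 h number 2, -0.18 without ear 0 h number 3 and -0.16 with quantile normalization. Antioxidant genes fell (-0.13, camera adjusted p = 0.0103; adjusted p = 0.663 with an estimated correlation), with Nqo1, a quinone reductase gene, at 215 ± 97.8 and 80.0 ± 41.3 TPM and the metallothionein gene Mt2 at 1.38. The antioxidant call was lost without ear 0 h number 1 (0.02) or ear 12 h number 2 (-0.19), and the median was -0.23 without ear 0 h number 2 and -0.20 without ear 12 h number 3. DNA repair genes fell (-0.10, camera adjusted p = 0.0297; adjusted p = 0.663 with an estimated correlation). The repair call was lost without ear 12 h number 1 (-0.07), ear 12 h number 3 (-0.07), ear 0 h number 2 (-0.12) or ear 0 h number 3 (-0.12) and without the filter (-0.10). The median was -0.19 without ear 12 h number 2. Senescence genes rose (0.16, camera adjusted p = 0.0403; adjusted p = 0.490 with an estimated correlation). Senescence was no longer called without the filter (0.16), with ear libraries alone (0.16), without either lung 12 h library (0.16), without ear 0 h number 1 (0.39), or without ear 12 h number 1 (0.15) or number 3 (0.31). The senescence median was 0.08 without ear 0 h number 3 and 0.36 without ear 12 h number 2. Targets of p53 fell (-0.12, camera adjusted p = 0.0403; adjusted p = 0.663 with an estimated correlation). The p53 list was no longer called without the filter (-0.12), with ear libraries alone (-0.12), with quantile normalization (-0.14) or upper-quartile scaling (-0.16), without either lung 12 h library (-0.12), without ear 0 h number 2 (-0.04) or number 3 (-0.12), or without ear 12 h number 1 (-0.01) or number 3 (-0.03). The p53 median was -0.23 without ear 12 h number 2. With the replicate number as a block, 2 more lists passed, matrix proteases (median 0.15) and collagens (median 0.16), each with an adjusted p of 0.0498. Without the block these had an adjusted p of 0.714 and 0.859 with an estimated correlation.

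Medians of the lists that did not pass in ear were -0.10 for mitochondrially encoded transcripts, -0.16 for mesothelial markers, 0.86 for melanocyte and Schwann markers, -0.31 for adipocyte markers, 0.09 for autophagy, 0.16 for interferon-stimulated genes, 0.19 for fibroblast markers, -0.13 for epithelial markers, -0.04 for alveolar markers, 0.02 for macrophage markers, 0.05 for smooth muscle markers, 0.02 for cholesterol biosynthesis, 0.02 for Hox genes, 0.00 for lung mesenchyme genes and -0.01 for apoptosis regulators. The median and the mean differed in sign for the stress response of unfolded proteins (0.03 and -0.04), heat shock chaperones (-0.01 and 0.01), skin, head and neural crest genes (-0.01 and 0.01), myofibroblast genes (0.07 and -0.01) and apoptosis regulators (-0.01 and 0.05). Of all these lists, 1 gene passed adjusted over the list alone, Des in the smooth muscle list, named there after its values were seen. Some of these lists passed when 1 library was left out. Without ear 0 h number 2, interferon-stimulated genes (0.44), melanocyte and Schwann markers (1.42), collagens (0.21), mitochondrially encoded transcripts (-0.24), adipocyte markers (-0.78) and myofibroblast genes (0.25) passed. Without ear 12 h number 2, matrix proteases (0.32), autophagy (0.21), mitochondrially encoded transcripts (-0.18) and, in the other direction, myofibroblast genes (-0.245) did. Without ear 12 h number 3, collagens (0.43), melanocyte and Schwann markers (1.35) and mitochondrially encoded transcripts (-0.18) passed, and without ear 12 h number 1 myofibroblast genes did (0.24). Without ear 0 h number 1, adipocyte markers (0.47), autophagy (0.24) and cholesterol biosynthesis (0.16) passed, and without ear 0 h number 3 adipocyte markers did (-0.77). Mitochondrially encoded transcripts turned without passing to 0.145 without ear 12 h number 1.

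In lung, Ccl12, which encodes a chemokine that attracts monocytes, rose from 1.70 ± 0.113 TPM at 0 h to 16.5 ± 2.97 TPM at 12 h (mean ± SD, n = 2; log2 fold change 2.68, SE 0.217, adjusted p = 0.0062). It was at 1.62 and 1.78 TPM at 0 h and at 14.4 and 18.6 TPM at 12 h. Ccl12 (ENSMUSG00000035352.3) lies on chromosome 11 at 82101845 to 82103400, among similar chemokine genes with which reads may be shared. Genes of the complement component C1q, made largely by macrophages, had similar values without passing the threshold. C1qb was at 2.29 ± 0.302 and 21.5 ± 12.5 TPM (2.66, SE 0.339, adjusted p = 0.148). C1qa was at 9.75 ± 0.518 and 75.7 ± 59.0 TPM (2.58, SE 0.450, adjusted p = 0.536), and C1qc was at 10.6 ± 4.60 and 88.7 ± 76.2 TPM (2.69, SE 0.539, adjusted p = 0.600). Clec12a, Cd72, Nxpe5, Lce1g and Il1rl1 had values of 3.13, 2.67, 2.13, 2.27 and 1.83. In the other direction Nsg1, Clca3a1, Ick, Peg10, Rpl22l1, Pml, Cdc42ep2 and Dcp2 had values of -1.27, -1.38, -1.04, -0.94, -0.88, -0.85, -0.77 and -0.76, and Nsg1 was at 237 ± 16.7 and 97.6 ± 3.08 TPM.

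In limma's test, 1 of 13188 genes, Ccl12, passed the threshold for 12 h against 0 h in lung. Unadjusted, 526 genes (3.99%, also below the share of 0.05 that would pass if no gene changed) had an unadjusted p under 0.05, 258 higher and 268 lower. The count was 0 without lung 0 h number 1, 0 without lung 0 h number 2 and 152 without lung 12 h number 1, of which 144 were higher and 8 lower. It was also 0 with the replicate number as a block, a pseudocount of 0.1, a filter of 5 TPM or lung libraries alone, and 7 without the filter.

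Macrophage markers rose in lung as a list. All 14 had higher means at 12 h, with a median of 1.18 (camera adjusted p = 3.26e-13; adjusted p = 0.834 with an estimated correlation). Of these, 0 passed over all genes and 3 (the C1q genes) adjusted over the list alone. The spread behind that count is shared with the ear libraries, where the 14 markers summed to 26.5 to 56.5 TPM. In lung they summed to 5364 to 17135 TPM, so the shared spread may be too small for lung. The size of the change came from lung 12 h number 2: the median was 0.19 without it and 2.15 without lung 12 h number 1. Lyz2 was at 6037 and 4775 TPM at 0 h and at 6451 and 13720 TPM at 12 h, Csf1r, the receptor gene of macrophage growth factor, at 18.5 and 4.92 TPM and at 10.2 and 111 TPM, and Cd68 at 181 and 105 TPM and at 124 and 603 TPM. The C1q genes and Ccl12, named for the smallness of their p, were higher in both 12 h libraries than in either 0 h library.

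**Figure D5:**
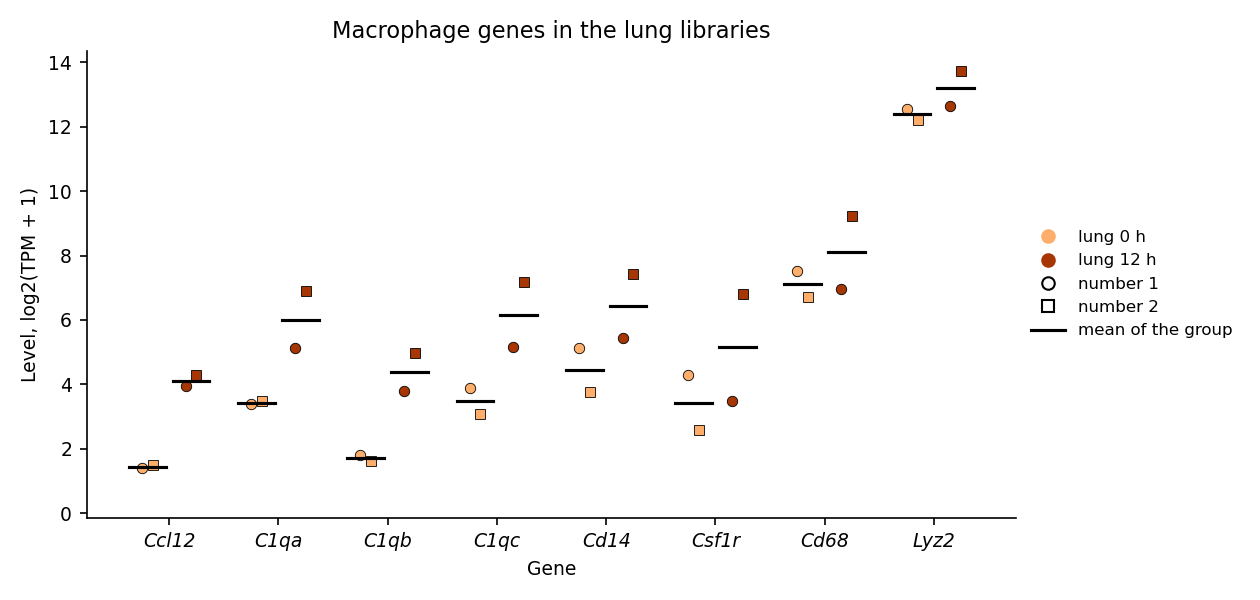
Levels of 8 macrophage genes in the 4 lung libraries in log2(TPM + 1), with a point for each library and a line at the mean of each group. Ccl12 and the C1q genes lie higher in both 12 h libraries, whereas Csf1r, Cd68 and Lyz2 stand out in 12 h number 2, at 111, 603 and 13720 TPM.

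Lysosomal and interferon genes rose beside the macrophage markers. Autophagy and lysosome genes had a median of 0.39, with 19 of 22 genes higher, 0 past the limma threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 4.67e-06; adjusted p = 0.834 with an estimated correlation). Lamp1, a lysosomal membrane gene, was at 518 ± 31.7 and 739 ± 155 TPM. The median was 0.11 without lung 12 h number 2 and 0.65 without number 1. Interferon-stimulated genes had a median of 0.36, with 0 of 22 genes over all genes and 1, Ifi27l2a, adjusted over the list alone (camera adjusted p = 1.58e-04; adjusted p = 0.834 with an estimated correlation). Ifi27l2a was at 3.16 ± 1.62 and 34.4 ± 16.7 TPM, and Oas1a had a value of 1.26. The interferon call was lost without lung 0 h number 1 (0.09) or lung 12 h number 1 (0.31), and the median was 0.57 without lung 0 h number 2.

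Lung identity genes fell as lists. All 12 lung mesenchyme genes had lower means at 12 h, 0 over all genes and 1 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 4.67e-06; adjusted p = 0.469 with an estimated correlation). Meox2, a homeobox gene, was at 7.09 ± 3.10 and 2.06 ± 0.391 TPM, and Tbx4, Tbx2 and Adh1 had values of -0.77, -0.59 and -1.27. That call was lost without lung 12 h number 2 (-0.36), and the median was -0.80 without lung 12 h number 1, -0.70 without lung 0 h number 1 and -0.27 without lung 0 h number 2. Of 15 Hox genes of the A and B clusters, the 14 that passed the filter had lower means, with a median of -0.48 (camera adjusted p = 1.55e-06; adjusted p = 0.834 with an estimated correlation). Of these, 0 passed the limma threshold over all genes and 0 adjusted over the list alone. Hoxa3 was at 9.20 ± 2.10 and 2.69 ± 1.65 TPM. The Hox call was lost without lung 12 h number 2 (-0.06), the library with the highest macrophage transcripts, and the median was -0.83 without lung 12 h number 1.

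Proliferation, ribosomal and epithelial genes also fell in lung, each list with 0 genes past the limma threshold over all genes and 0 adjusted over the list alone. G2/M genes had a median of -1.13 (camera adjusted p = 1.80e-07; adjusted p = 0.834 with an estimated correlation) and S phase genes of -0.59 (camera adjusted p = 2.44e-04; adjusted p = 0.987 with an estimated correlation), with Cdc20 at -1.54 and Tyms at -1.11. Without lung 12 h number 1 these medians were -0.11 and 0.35 and both calls were lost, the S phase direction turning. Without lung 12 h number 2 they were -2.13 and -1.50, and the S phase call was also lost without lung 0 h number 1 (-0.48). Ribosomal protein genes had a median of -0.28, with 35 of 36 lower (camera adjusted p = 4.81e-10; adjusted p = 0.834 with an estimated correlation), and Rpl10a was at 1905 ± 315 and 1145 ± 23.3 TPM. The median was -0.18 without lung 0 h number 1 and -0.15 with quantile normalization. Epithelial and keratinocyte markers had a median of -0.61 (camera adjusted p = 0.0186; adjusted p = 0.834 with an estimated correlation), with Krt18 at -0.86. That call was lost with the replicate number as a block (adjusted p = 0.0539), without the filter (-0.19), with a filter of 5 TPM (-0.70), with a pseudocount of 0.1 (-0.71), without lung 12 h number 1 (-0.20) and without lung 0 h number 1, where the median turned to 0.05. It was -0.97 without lung 0 h number 2 and -0.93 without lung 12 h number 2. Myofibroblast genes, with a median of 0.34 and an adjusted p of 0.0514, passed with the block (adjusted p = 0.0011; without it, adjusted p = 0.987 with an estimated correlation).

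Lists that did not pass in lung had medians of -0.17 for hypoxia, 0.23 for mitochondrially encoded transcripts, -0.13 for DNA repair, -0.15 for heat shock chaperones, 0.29 for endothelial, 0.25 for mesothelial, 0.53 for melanocyte and Schwann and -0.14 for skeletal muscle markers. They were -0.09 for cholesterol biosynthesis, -0.16 for immediate early genes, -0.10 for the stress response of unfolded proteins, 0.14 for adipocyte markers, -0.03 for fatty acid oxidation, -0.06 for collagens, 0.06 for apoptosis regulators, -0.13 for alveolar markers, -0.19 for matrix proteases, -0.04 for senescence genes, 0.01 for p53 targets, -0.01 for oxidative phosphorylation and 0.00 for skin, head and neural crest genes. The median and the mean differed in sign for NF-kB genes (0.04 and -0.07), smooth muscle markers (0.04 and -0.07), chondrocyte markers (-0.04 and 0.04), glycolysis (-0.10 and 0.02), antioxidant genes (0.02 and -0.02) and fibroblast markers (0.05 and -0.07). Of these lists, 1 gene passed adjusted over the list alone, Upk1b in the mesothelial list (1.14), named after its values were seen. Some of these lists passed when 1 library was left out. Without lung 0 h number 1, hypoxia (-0.66), collagens (-0.55) and myofibroblast genes (0.49) passed. Without lung 0 h number 2, mitochondrially encoded transcripts (0.44), collagens in the other direction (0.38), melanocyte and Schwann markers (1.06), cholesterol biosynthesis (-0.15) and immediate early genes (-0.32) did, and hypoxia was 0.285 without passing. Without lung 12 h number 1, hypoxia passed (-0.59) and mitochondrially encoded transcripts turned to -0.19. Without lung 12 h number 2, mitochondrially encoded transcripts (0.63), DNA repair (-0.28), antioxidant (-0.47) and myofibroblast genes (0.64) passed.

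Whether the 12 h change differed between the tissues was tested by the interaction term. Skeletal muscle markers differed by -2.06, the median of lung change minus ear change (camera adjusted p = 5.16e-15, or 0.389 with an estimated correlation). Of the 9, 0 genes passed the limma threshold over all genes and 8 adjusted over the list alone. Macrophage markers moved 1.24 further in lung, with 0 of 14 genes over all genes and 3 adjusted over the list alone (camera adjusted p = 1.30e-10; adjusted p = 0.724 with an estimated correlation). The macrophage difference was 0.12 without lung 12 h number 2, 2.18 without lung 12 h number 1 and 0.77 without lung 0 h number 2. Lung mesenchyme genes differed by -0.66, with 0 of 12 genes past the limma threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 1.28e-05; adjusted p = 0.389 with an estimated correlation), and by -0.39 without lung 12 h number 2. Myofibroblast genes differed by 0.37 without passing (adjusted p = 0.0971) and passed with the replicate number as a block (adjusted p = 0.0020; without it, adjusted p = 0.809 with an estimated correlation). Among genes, Ccl12 had the smallest adjusted p, 0.0710 (2.61, SE 0.280). C1qb, Clec12a, Slc37a3 and Ifi27l2a had values of 2.67, 3.17, 1.34 and 3.60, and Actc1, Ick, Ypel4 and Slco3a1 of -4.05, -1.54, -1.52 and -1.17. In limma's test, 387 genes (2.93%) had an unadjusted p under 0.05 for the interaction, 111 higher and 276 lower. That share is also below the 0.05 that would pass if no gene changed. After adjustment, 0 of 13188 genes passed the threshold. Without lung 12 h number 1 the count was 27, and it was 1 (Ccl12) without the trend or under either scaling and 2 without the filter.

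The changes of the tissues showed no relation across genes beyond that of other splits. The log2 fold changes of 12 h against 0 h in ear and lung correlated at 0.092 (Pearson) and 0.087 (Spearman) over 13188 genes, and genes are not independent replicates. Of the 30 ways to combine the splits of the ear and lung libraries, 18 gave a correlation at least as large in size. These splits include ones that do not part the ear libraries of equal number.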

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

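Leaving out each library was set beforehand. Its use to weigh 1 library as a source of values, and the splits below, were chosen after the results were seen.

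In the interaction test, 13 lists passed with the preset correlation and 0 of them with an estimated correlation (adjusted p values of 0.389 to 0.809). Values are the median over a list's genes of the log2 change in lung minus that in ear. They were -2.06 for skeletal muscle markers, 1.24 for macrophage markers, -0.66 for lung mesenchyme genes, -0.49 for Hox genes, -0.60 for hypoxia, 0.36 for autophagy and lysosome and 0.25 for interferon-stimulated genes. They were -0.52 for immediate early genes, 0.84 for chondrocyte markers, 0.32 for mitochondrially encoded transcripts, 0.71 for mesothelial markers, -0.15 for ribosomal protein genes and 0.059 for oxidative phosphorylation. Over all genes 0 genes of these lists passed in limma, and adjusted over the list alone 8 muscle, 3 macrophage and 1 interferon-stimulated gene did.

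Of these 13 differences, those of muscle, macrophage and lung mesenchyme genes passed whichever library was left out. Hox genes no longer passed without lung 12 h number 2 (-0.11), and their value was -0.86 without lung 12 h number 1. Hypoxia no longer passed without lung 0 h number 2 (-0.13) or lung 12 h number 2 (-0.13), and its value was -1.02, -1.22, -0.40 and -0.95 without lung 0 h number 1, lung 12 h number 1, ear 12 h number 1 and ear 12 h number 2. Autophagy was lost without lung 0 h number 2 (0.29) or ear 12 h number 2 (0.27), and was 0.58, 0.10 and 0.20 without lung 12 h number 1, lung 12 h number 2 and ear 0 h number 1. Interferon-stimulated genes were lost without lung 0 h number 1 (-0.02), lung 12 h number 1 (0.17), ear 0 h number 2 (-0.04) or ear 12 h number 3 (0.05), and were at 0.46 and 0.08 without lung 0 h number 2 and lung 12 h number 2. Immediate early genes were lost without lung 0 h number 1 (-0.32), lung 12 h number 1 (-0.21), ear 0 h number 1 (-0.43) or ear 12 h number 1 (-0.19), and were at -0.88, -0.94 and -0.84 without lung 0 h number 2, lung 12 h number 2 and ear 0 h number 3. Chondrocyte markers were lost without lung 0 h number 2 (0.78), lung 12 h number 1 (0.84), ear 0 h number 1 (0.43) or ear 12 h number 3 (0.52). Mesothelial markers were lost without lung 0 h number 2 (0.81) or lung 12 h number 1 (0.43), and were at 0.47 without ear 0 h number 1. Ribosomal genes were lost without lung 0 h number 1 (-0.05), lung 12 h number 2 (-0.07), ear 0 h number 1 (-0.05), ear 12 h number 2 (-0.13) or ear 12 h number 3 (-0.10), and were at -0.24 without lung 0 h number 2 or lung 12 h number 1. Mitochondrially encoded transcripts were lost without lung 0 h number 1 (0.04), lung 12 h number 1 (-0.14), ear 0 h number 1 (0.22), ear 0 h number 3 (0.30) or ear 12 h number 1 (0.06), and were at 0.59 and 0.69 without lung 0 h number 2 and lung 12 h number 2. Oxidative phosphorylation was lost without lung 0 h number 2 (0.04), lung 12 h number 1 (0.03), ear 0 h number 3 (0.06) or ear 12 h number 1 (0.01), and was 0.13, 0.16, 0.10, 0.13 and 0.14 without lung 0 h number 1, lung 12 h number 2, ear 0 h number 1, ear 0 h number 2 and ear 12 h number 3.

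Other settings ended some of these calls too. Mesothelial markers no longer passed with a filter of 5 TPM (0.13), upper-quartile scaling (0.72) or a pseudocount of 0.1 (0.66), and chondrocyte markers with a filter of 5 TPM (1.11) or a pseudocount of 0.1 (0.98). With quantile normalization and upper-quartile scaling, the values were 0.34 and 0.34 for mitochondrially encoded transcripts, 0.11 and 0.08 for oxidative phosphorylation and -0.06 and -0.13 for ribosomal protein genes, and none of these passed. Ribosomal protein genes were also lost without the filter (-0.15). With a pseudocount of 0.1 the values were -0.77 for Hox genes and -3.62 for skeletal muscle markers, and without the filter 0.46 for mesothelial markers, each still passing.

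The higher skeletal muscle transcripts in ear at 12 h did not come from 1 library. The list median was 1.52 without ear 12 h number 3, the library with the most muscle transcripts, and 1.85 without ear 0 h number 2, the library with Y-linked transcripts. Muscle-lineage cells in the samples remain a candidate source: muscle genes outside the list had a median of 0.70, with 11 of 12 higher, which leaves this open. Of the 10 splits of the 6 ear libraries, 1 gave a list median as large as the real 1.98, and the highest other was 1.32; 10 splits cannot give a share under 0.05. A change with time after death, which the design names, stays open as untested.

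The size of the higher macrophage values in lung at 12 h rested on lung 12 h number 2, without which the list median was 0.19 and the list still passed (adjusted p = 0.0015). Macrophage genes outside the list were 1.98 above the lung 0 h mean in that library, with 20 of 20 higher, and 0.04 above it in lung 12 h number 1, with 11 of 20 higher, which is consistent with more macrophages in number 2. C1qa, C1qb, C1qc and Ccl12 had a median of 1.88 without that library, but they were chosen for their change in these libraries, so this value decides nothing about its source. A change with time after death stays open as untested.

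The calls of lower G2/M genes at 12 h rested on 1 library in each tissue, without which they were lost. The median was -0.00 without ear 12 h number 1 (-0.003 before rounding) and -0.11 without lung 12 h number 1. No biological explanation for those 2 libraries was tested, and time after death stays open as untested.

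In limma's test of ear at 12 h against 0 h, 0 genes passed and 219 had an unadjusted p under 0.05. With a real count of 0, all 10 of the 10 splits of the 6 ear libraries must give as many called genes, so that comparison says nothing; the highest other was 5. Of the 10 splits, 8 gave as many at an unadjusted p, the highest other being 1736. The 10 splits cannot give a share under 0.05. Splits that, like the real one, part all 3 pairs of equal number gave 64, 289 and 109. The split with 1736, which sets ear 0 h number 1, 12 h number 1 and 12 h number 3 against the rest, points to a structure of the samples other than time.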

How the results depend on the processing

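The alternatives named above as added later were chosen after the data were seen.

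For 12 h against 0 h in ear, 0 genes passed limma's threshold under every alternative run. In lung the count of 1 became 7 without the filter: Ccl12, and Trpm2, Hoxc5, Slc28a2, Rxfp1, Gvin1 and Prss46. It became 0 with a filter of 5 TPM, a pseudocount of 0.1, lung libraries alone, the replicate block, a term for Y-linked transcripts or without the libraries that hold them, and ranged from 0 to 152 when 1 library was left out. With the crossed pairing of the lung libraries it was 0. For the interaction the count of 0 became 2 without the filter (Ccl12 and Slc28a2), 1 (Ccl12) without the trend, with quantile normalization or with upper-quartile scaling, and 2 with transcripts in place of genes (of Ick and Elmod3), and ranged from 0 to 27 when 1 library was left out. These genes were named after their values were seen. For lung against ear the 0 h count of 1488 was 745 with the replicate block across tissues, 551 without the libraries with Y-linked transcripts and 2368 with array weights, and ranged from 549 to 1766 when 1 library was left out. The 12 h count of 2267 was 1164 with the replicate block across tissues and 1475 with array weights, and ranged from 1369 to 2470. Where fewer libraries or a block were used, fewer degrees of freedom remained; otherwise the cause was not tested.

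With an estimated correlation the lists past the threshold numbered 0 of 16 in ear, 0 of 9 in lung, 0 of 13 for the interaction, 2 of 15 at 0 h and 1 of 16 at 12 h. With fry they numbered 0, 0 and 0 for the first 3, 9 at 0 h and 12 at 12 h, of which 11 were among the 16. Leaving out 1 library gave 10 to 19 lists in ear, 6 to 14 in lung, 9 to 16 for the interaction, 13 to 17 at 0 h and 14 to 20 at 12 h, and 14 passed in lung without the libraries with Y-linked transcripts.

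Some directions turned, and the cause was not tested. With array weights, fatty acid oxidation in ear had a median of 0.04 (0.043), immediate early genes 0.08 (0.076, the test turning), Etfa a log2 fold change of 0.04 (0.042) and Decr1 0.03 (0.030). Leaving out 1 library gave ranges of -0.24 to 0.07 (-0.240 to 0.073) for fatty acid oxidation in ear, -1.50 to 0.35 for S phase genes in lung and -0.97 to 0.045 for epithelial markers in lung. In lung, the Cldn4 log2 fold change, lung 12 h vs 0 h, ranged from -1.87 to 0.10, turning without lung 0 h number 1, and the Krt8 log2 fold change, lung 12 h vs 0 h, from -1.64 to 0.045, turning without lung 0 h number 1 or lung 12 h number 1 (0.019). Mitochondrially encoded transcripts turned without lung 12 h number 1 in the interaction (range -0.14 to 0.69) and in the test at 12 h (0.011 to 0.71), and ribosomal genes in the interaction test without ear 0 h number 1 (-0.053).

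Alternatives added later ended further list calls, and the cause was not tested. Array weights ended those of antioxidant (-0.04), oxidative phosphorylation (-0.01) and senescence genes (0.16) in ear, of adipocyte markers at 0 h (-0.74), and of collagens (-0.40), interferon-stimulated genes (-0.65) and mitochondrially encoded transcripts (0.21) at 12 h. In the interaction they ended those of immediate early genes (-0.33), mitochondrially encoded transcripts (0.05) and oxidative phosphorylation (-0.02). Without the libraries with Y-linked transcripts, the calls of DNA repair (-0.12), glycolysis (0.19) and p53 targets (-0.04) in ear and of glycolysis (0.14) and hypoxia (0.04) at 0 h were lost. So were those of autophagy (0.32), hypoxia (0.01), interferon-stimulated genes (0.23), mesothelial markers (0.80) and oxidative phosphorylation (0.08) in the interaction. A term for those transcripts ended the calls of DNA repair (-0.12) and p53 targets (-0.07) in ear and of oxidative phosphorylation in the interaction (0.05), and the replicate block across tissues that of ribosomal genes in the interaction (-0.19). A pseudocount of 0.1, which by construction enlarges differences of low genes, gave medians at 0 h of 5.48 for Hox genes, 5.91 for macrophage markers, -5.33 for chondrocyte markers, -3.91 for skin, head and neural crest genes and 2.60 for alveolar markers. Without the filter, which admits genes near 0, the medians of the last and of smooth muscle markers were 0.51 and 0.46. At 12 h the pseudocount of 0.1 gave 4.58 for Hox genes and -5.07 for skeletal muscle markers. Other values grew with the alternatives added later. In the interaction, immediate early genes were at -1.11 with the block across tissues, against -0.52. Mitochondrially encoded transcripts were at 0.74 there without the libraries with Y-linked transcripts, against 0.32. In lung, interferon-stimulated genes were at 0.69 with the term for those transcripts, against 0.36.

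Of the alternative values for genes, 5065 kept their direction and side of the threshold, 263 lost the call, 52 gained one and 5 turned; for lists 1318 kept it, 199 lost it and 8 turned. The replicate block within a tissue changed no calls in the time contrasts and the interaction beyond those of Ccl12 and of the epithelial, myofibroblast, matrix protease and collagen lists. The depth behind each value is unknown, so what it limits was not measured.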

Other observations

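All values here were chosen after the data were seen. Metallothionein genes, which encode metal-binding proteins, separated the ear libraries without regard to time. Mt2 was at 889, 1320 and 1338 TPM in ear 0 h number 1, 12 h number 1 and 12 h number 3, and at 107, 164 and 157 TPM in ear 0 h numbers 2 and 3 and 12 h number 2. The mitochondrial superoxide dismutase gene Sod2 was at 238, 314 and 269 TPM in the same 3 libraries and at 65.3, 70.4 and 78.5 TPM in the others. In limma's test of that split Mt1, Mt2, Sod2, Car9 and Sptssb passed, with adjusted p values of 0.0149, 0.0174, 0.0156, 0.0061 and 0.0242. In the split of ear 0 h numbers 1 and 3 and 12 h number 3 against the rest, Rflnb passed (adjusted p = 0.0277).

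Adipocyte genes were high in ear 0 h number 1. Fabp4, which encodes a fatty acid carrier, was at 2070 TPM there and at 65.9 to 191 TPM in the other ear libraries, and Adipoq, a fat cell hormone gene, was at 34.3 TPM against 0.675 to 8.23 TPM. The Y-linked gene Uty was at 33.3 to 89.2 TPM in all 10 libraries, including those where Ddx3y and Eif2s3y were below 1 TPM. The reason was not tested, and its level was not used to tell libraries apart.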
